A study of Homo sapiens with 6 samples.

How the data were processed

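RNA was sequenced from 3 libraries of BEAS-2B cells and 3 libraries of 2B-NNK cells. Per the labels, both lines were kept in the same bronchial basal medium with serum, and 2B-NNK cells had been given NNK at 100 mg per litre for 24 h every 4 days up to a total of 1 mg. Total RNA was extracted with TRIzol and 1.3 ug entered a stranded library kit, per the labels' protocols. HISAT2 2.1.0, cutadapt 1.17 and the build GRCh37 are named in the submitters' processing notes without a role. The program that assigned reads to transcripts, its annotation and its use of strand are not given in the sources used here.

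The authors deposited 1 table of transcripts with an FPKM value per library, normalized for transcript length and library size per the file headers. The table lists protein-coding transcripts whose higher group mean is at least 0.5 FPKM, so tests over it are conditional on that selection. The columns of group means, headed FPKM in the deposited table, hold the mean of log2(FPKM + 1), from which they differed by at most 5.0e-14, and were not used in any test. The authors also deposited a log2 fold change, a p-value and a q-value per transcript. The deposited p-values lay within 1% of those of an equal-variance linear model on log2(FPKM + 1) for 100.0% of transcripts. The deposited q-values were larger than a Benjamini-Hochberg adjustment over the listed transcripts alone gives. Under that adjustment 98 transcripts have q under 0.05, and the smallest q is 0.0012 against a deposited 0.0023.

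FPKM values are not counts, and steps of whole reads were not seen in the low values (highest periodicity 0.11, against 0.14 after random stretching of each value, where 1 is perfect steps). The depth of the libraries is therefore unknown, and no counting interval is given. Values listed at exactly 0 made up 9.0, 10.8 and 14.6% of transcripts in BEAS-2B replicates 1, 2 and 3 and 6.3, 13.6 and 12.9% in the corresponding 2B-NNK libraries. An exact 0 can be a failed estimate, so genes listed at 0 in a library are given by library.

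The value of a gene is the sum of the FPKM of its listed transcripts, with a median of 2 listed transcripts per gene. Genes or transcripts with at least 0.5 FPKM in at least 3 of the 6 libraries were tested. Values were put on the log2(FPKM + 1) scale and fitted with limma 3.58.1 in R 4.3.3, with a trended and robust prior, the line as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are 2B-NNK minus BEAS-2B on this scale. The smallest two-sided p of an exact permutation test of 3 against 3 libraries is 0.1, so no single gene could pass such a test. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, where at least 5 members were measured, again with an estimated correlation, and with fry, with adjustment over the tested lists. For each list, p-values of its members were also adjusted over the list alone.

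The tests, the lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule names RRM2 and C2orf48, then the 6 genes with the largest rise and the 6 with the largest fall among changed genes whose groups do not overlap and whose higher mean is at least 5 FPKM. Names that are only a clone or locus identifier, Y-linked genes and XIST were left out. It then names in each list the 2 members with the largest rise and the 2 with the largest fall among those past the test or, where none passed, the member with the highest mean. KRT8 and KRT18 were named after their values were seen. The lists cover ribonucleotide reductase, S phase, G2 and mitosis, p53 targets, DNA repair, xenobiotic metabolism, NRF2 targets, epithelial junctions and keratins, mesenchymal genes, matrix proteases, interferon response, NF-kB and cytokines, antigen presentation, hypoxia and glycolysis, cholesterol biosynthesis, the unfolded protein and amino acid response, ERK output, YAP and TGF-beta targets, Wnt and Notch, cancer-testis antigens, lung cancer drivers, mitochondrial genes, histones, ribosomal proteins, housekeeping genes, and markers of ciliated, secretory, basal, alveolar, fibroblast, endothelial, leukocyte, neuroendocrine, and hepatocyte or kidney cells.

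The scripts were tested on simulated libraries with 200 planted changes among the tested features. Among 11423 simulated genes the fit recovered 12% of 100 changes of 1 log2 unit and 67% of 100 changes of 2 log2 units, with 2 false calls of 81. Among 24558 simulated transcripts it recovered 0% of either size. Alternatives covered the pseudocount, the filter, the scaling, the moderation, the replicate number as a block, the most abundant transcript in place of the sum, and leaving out each library. A correction for GC content and log2 length was added after the data were seen. It subtracts from each library a loess surface with span 0.3, using the GENCODE 29 sequence of the most abundant listed transcript, matched by identifier for 99.6% of transcripts. Coordinates are those of the deposited table on GRCh37. Python packages numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used to read the table. C2orf48 and the chimeric RNA were not analysed here. A result of the named gene rule and the list it belongs to are not reported here.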

Results

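RNA sequencing was compared between BEAS-2B, an immortalised line of human bronchial epithelial cells, and 2B-NNK, the malignantly transformed line derived from it by exposure to NNK, a tobacco-specific nitrosamine. Each line had 3 libraries. The abundance of 29656 protein-coding transcripts, listed under 11797 gene names on GRCh37, was given as FPKM, a read abundance scaled by transcript length and library size. The FPKM of the listed transcripts summed to 342274, 346718 and 383040 in BEAS-2B replicates 1, 2 and 3, and to 351831, 351423 and 376513 in the corresponding 2B-NNK libraries. Between 10807 and 11251 genes per library reached 0.5 FPKM. The number of reads behind these values is unknown, so no counting interval is given. Nothing in the labels says that the libraries of a line came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

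The series title names a chimeric RNA of RRM2 and C2orf48. RRM2, the small subunit of ribonucleotide reductase, which makes deoxynucleotides for DNA synthesis, stood at 57.5 ± 15.4 FPKM (SD, n = 3) in BEAS-2B and 42.4 ± 8.17 FPKM (SD, n = 3) in 2B-NNK. The libraries held 71.1, 60.6 and 40.8 FPKM in BEAS-2B and 36.0, 51.6 and 39.5 FPKM in 2B-NNK, so the groups overlapped. The log2 fold change of -0.41 (SE 0.26) did not pass the test (limma, adjusted p = 0.428). The value summed 4 listed transcripts within chromosome 2, 10262455 to 10271546 on the plus strand of GRCh37. RRM2-202 was the most abundant, at 24.2 ± 17.4 FPKM (SD, n = 3) in BEAS-2B and 21.2 ± 5.17 FPKM (SD, n = 3) in 2B-NNK. Its libraries held 34.6, 33.8 and 4.11 FPKM in BEAS-2B and 17.6, 27.1 and 18.8 FPKM in 2B-NNK. Its log2 fold change of 0.24 (limma, adjusted p = 0.945) had the opposite sign to the difference of its mean FPKM, because of the low value of BEAS-2B replicate 3. The log2 fold changes of RRM2-201, RRM2-206 and RRM2-212 were -1.18, -0.52 and -0.31, and none of them passed the test (limma, adjusted p = 0.726, 0.627 and 0.767). RRM1, the large subunit of the enzyme, stood at 65.9 ± 35.6 FPKM (SD, n = 3) in BEAS-2B and 61.1 ± 37.5 FPKM (SD, n = 3) in 2B-NNK (log2 fold change -0.14, limma, adjusted p = 0.907). Of the 3 measured members of the ribonucleotide reductase list, 0 passed the test, over all genes or adjusted over the list alone. C2orf48 and the chimeric RNA itself were not analysed here, as 0 of the listed transcripts were named for C2orf48 or for both genes together.

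The comparison of the lines as a whole asks which genes differ between the transformed line and its parent. With 1 line of each kind, transformation, NNK exposure and time in culture cannot be told apart. Genes that were nearly silent in BEAS-2B and abundant in 2B-NNK included CYBA, the small membrane subunit of the NADPH oxidases, which rose from 0.357 ± 0.306 to 63.8 ± 16.9 FPKM (SD, n = 3), and PLAC8, a small cysteine-rich protein, which rose from 1.04 ± 0.325 to 41.3 ± 10.1 FPKM (SD, n = 3). COL6A2, a chain of type VI collagen, rose from 4.73 ± 0.675 to 70.1 ± 11.1 FPKM (SD, n = 3), and APOE, a lipid transport protein, rose from 0.899 ± 0.439 to 23.3 ± 10.7 FPKM (SD, n = 3). The keratins of simple epithelia KRT7 and KRT19 fell, KRT7 from 201 ± 65.3 to 9.72 ± 1.76 FPKM (SD, n = 3) and KRT19 from 13.1 ± 7.28 to 0.458 ± 0.135 FPKM (SD, n = 3). CSF2, which encodes the cytokine GM-CSF, fell from 24.4 ± 2.34 to 2.19 ± 1.11 FPKM (SD, n = 3).

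On the log2(FPKM + 1) scale, which understates the change of low genes, the largest rises were 5.57 for CYBA (SE 0.27), 4.59 for NDUFC1 (SE 0.44), 4.36 for PLAC8 (SE 0.26), 3.82 for CHAC1 (SE 0.50), 3.63 for COL6A2 (SE 0.20) and 3.60 for APOE (SE 0.39). Adjusted p lay between 0.00142 and 0.0127 (limma). NDUFC1, a subunit of respiratory complex I, stood at 0.541 ± 0.395 FPKM (SD, n = 3) in BEAS-2B and 39.2 ± 21.1 FPKM (SD, n = 3) in 2B-NNK, and 4 of its 6 annotated protein-coding transcripts were listed. CHAC1, an enzyme that degrades glutathione, was listed at 1.61, 0 and 0.176 FPKM in BEAS-2B and at 10.4, 30.4 and 23.02 FPKM in 2B-NNK. Its call was lost without BEAS-2B replicate 2 (limma, adjusted p = 0.0565) and without 2B-NNK replicate 3 (limma, adjusted p = 0.061). The largest falls were -4.19 for KRT7 (SE 0.30), -3.73 for KRT81 (SE 0.26), -3.16 for KRT19 (SE 0.36), -3.16 for GLUL (SE 0.26) and -3.05 for CSF2 (SE 0.29), beside FABP5, with adjusted p between 0.00142 and 0.00935 (limma). The fatty acid carrier FABP5 stood at 11.3, 10.98 and 9.04 FPKM in BEAS-2B and was listed at 0 in all 3 2B-NNK libraries. GLUL, glutamine synthetase, was listed at 10.1, 9.09 and 8.995 FPKM in BEAS-2B and at 0.57, 0 and 0 FPKM in 2B-NNK. For NDUFC1 and GLUL, whether reads were assigned to other entries was not tested, so values near 0 may not be absence of expression. KRT81, a hair keratin, stood at 15.6 ± 4.16 FPKM (SD, n = 3) in BEAS-2B and 0.237 ± 0.141 FPKM (SD, n = 3) in 2B-NNK, and its close sequence copies, like the pseudogenes of FABP5, leave the assignment of reads uncertain.

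**Figure D1:**
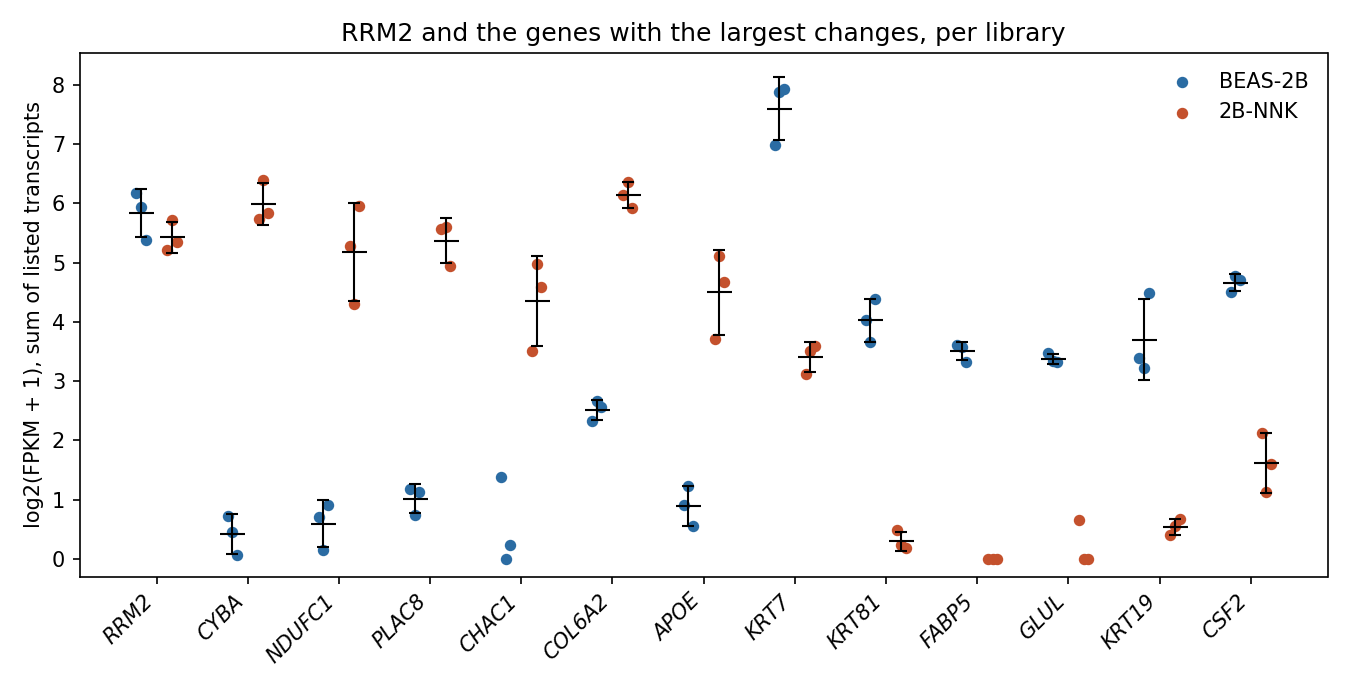
Abundance of RRM2 and of the genes with the largest rises and falls, as log2(FPKM + 1) of the sum of listed transcripts (vertical axis), with 1 point per library (BEAS-2B blue, 2B-NNK red). Horizontal marks and bars show the mean and SD of the 3 libraries of a line and are left out where a library is listed at 0. The points of the lines overlap for RRM2, whose log2 fold change was -0.41, and are apart for the other genes.

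Of 11423 genes tested, 530 changed, 398 of them higher and 132 lower in 2B-NNK (limma, adjusted p under 0.05), and 457 changed at least 2-fold. The 3 values of a line lay all above those of the other for every one of the 530 changed genes and for 27.4% of all tested genes, against 10% by chance. Higher genes made up 75.1% of the changed genes as deposited, 60.7% after quantile normalization, 60.5% with libraries scaled to 1 median and 55.4% after a correction for GC content and transcript length, which called 290 higher and 233 lower genes. The median log2 fold change over all tested genes was 0.07 as deposited, -0.02 after quantile normalization or the GC and length correction, and -0.03 with libraries scaled to 1 median. Across genes, the deviation of a library from the gene mean was rank correlated with GC content at -0.43, -0.30 and 0.18 in BEAS-2B and at 0.13, 0.34 and 0.09 in 2B-NNK. The count fell to 168, 70 and 281 genes without BEAS-2B replicates 1, 2 and 3, and to 237, 113 and 68 genes without 2B-NNK replicates 1, 2 and 3. Of 50 named genes past the test, 14 passed it without any 1 library, namely CYBA, NDUFC1, PLAC8, COL6A2, APOE, KRT7, KRT81, FABP5, GLUL, KRT19, CSF2, BTG2, PFKFB3 and TPPP3, and the other 36 lost the call without at least 1 library.

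**Figure D2:**
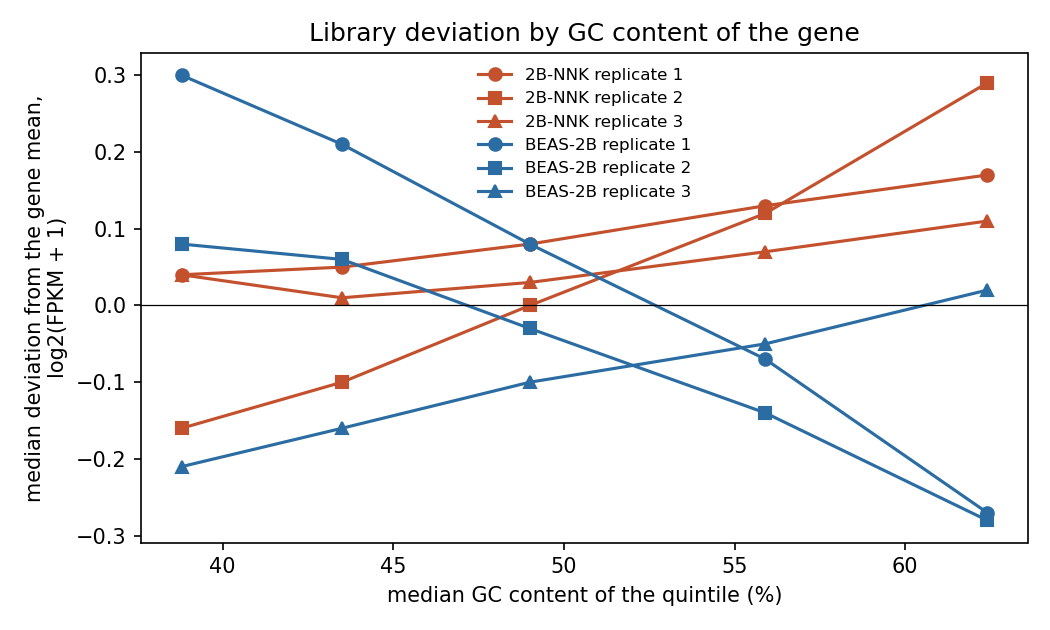
Median deviation of each library from the gene mean, in log2(FPKM + 1) (vertical axis), over 5 bins of genes ordered by GC content (horizontal axis, median GC in percent). The lines of BEAS-2B replicates 1 and 2 fall from 0.30 and 0.08 to -0.27 and -0.28, while those of BEAS-2B replicate 3 and of 2B-NNK replicates 1 and 2 rise from -0.21, 0.04 and -0.16 to 0.02, 0.17 and 0.29. The line of 2B-NNK replicate 3 goes from 0.04 to 0.11.

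Epithelial and mesenchymal genes were examined because transformed epithelial cells can change these programmes. Among 14 measured members of the list of epithelial junctions and keratins, KRT7 and KRT19 fell and 0 rose, over all genes and adjusted over the list alone, with a median log2 fold change of -0.35. The full list had 30 members, and CDH1, ESRP1, ESRP2, GRHL2 and KRT5 were among those not tested. The list passed limma's camera test (adjusted p = 0.0016), but not with an estimated correlation (adjusted p = 0.276 with an estimated correlation). The estimate was -0.04, below the preset 0.01, so the lost call does not show that its members were correlated. The other main keratins of simple epithelia, KRT8 (331 ± 141 and 328 ± 26.5 FPKM, SD, n = 3) and KRT18 (169 ± 52.6 and 187 ± 13.4 FPKM, SD, n = 3), did not pass the test. The mesenchymal list went both ways, with 3 of 25 measured members higher and 3 lower, or 7 higher and 8 lower adjusted over the list alone (median -0.52, camera adjusted p = 0.145). It passed downward without 2B-NNK replicate 1 (camera adjusted p = 0.0117). ACTA2, smooth muscle actin, rose by 1.71 on the log2 scale from 2.63 ± 0.267 to 10.95 ± 1.70 FPKM (SD, n = 3), and COL6A1, another chain of type VI collagen, rose by 1.49. CNN1, an actin-binding protein of smooth muscle, fell by 1.94, and TGFBI, an adhesion protein of the matrix, fell by 1.40 from 266 ± 54.6 to 99.1 ± 9.55 FPKM (SD, n = 3). In the list of matrix proteases and inhibitors 1 of 15 measured members rose and 2 fell, the same counts adjusted over the list alone (median -0.16, camera adjusted p = 0.145). ADAMTS1 rose by 1.49, and the proteases MMP3 and PLAU, which encodes urokinase, fell by 1.43 and 0.96.

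Immune genes moved in different directions by list. In the antigen presentation list 3 of 14 measured members rose and 0 fell, or 9 rose and 1 fell adjusted over the list alone (median 0.78, camera adjusted p = 0.00117; adjusted p = 0.276 with an estimated correlation). HLA-E rose by 1.15 on the log2 scale from 60.2 ± 6.24 to 135 ± 17.9 FPKM (SD, n = 3), and HLA-F rose by 1.63 (SE 0.28). After the GC and length correction its log2 fold change was 1.30 (SE 0.27) and did not pass (limma, adjusted p = 0.0532). The HLA class I genes are close sequence copies, so reads may be split among them. Interferon response genes had 2 of 26 measured members higher and 0 lower, or 5 higher and 0 lower adjusted over the list alone (median 0.57, camera adjusted p = 0.00117; adjusted p = 0.366 with an estimated correlation). MX1, an antiviral GTPase, was listed at 0.026, 1.05 and 0 FPKM in BEAS-2B and at 6.18, 5.93 and 6.46 FPKM in 2B-NNK, and USP18, which removes ISG15 from proteins, rose by 1.13. Among 23 measured members of the list of NF-kB and inflammatory cytokines, 4 fell and 1 rose, or 6 fell and 1 rose adjusted over the list alone (median -0.57, camera adjusted p = 0.00128; adjusted p = 0.475 with an estimated correlation). Beside CSF2, the neutrophil attractant CXCL8 fell by 1.77 from 246 ± 72.4 to 73.4 ± 31.5 FPKM (SD, n = 3), while the cytokine IL32 rose by 1.21 from 53.3 ± 7.24 to 126 ± 28.996 FPKM (SD, n = 3).

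**Figure D3:**
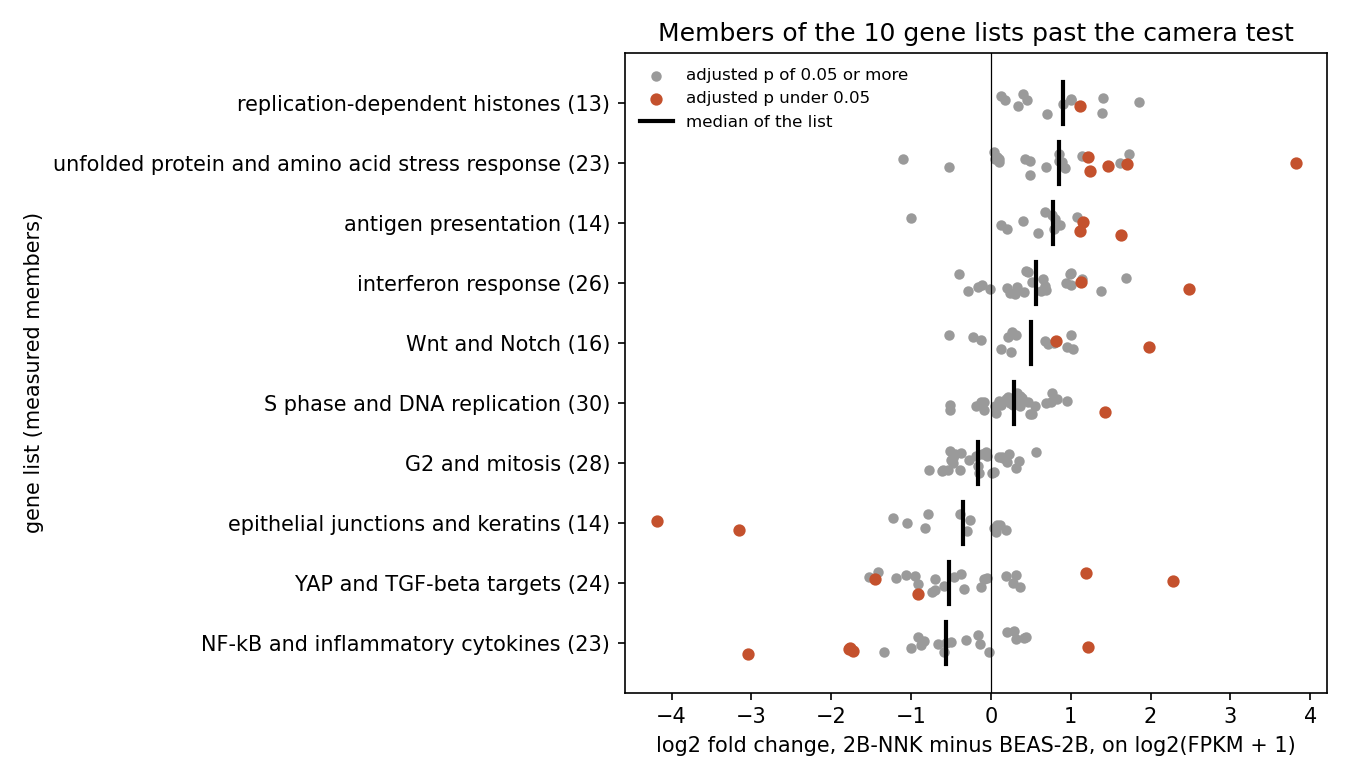
Log2 fold change of each measured member (points, 2B-NNK minus BEAS-2B on log2(FPKM + 1), horizontal axis) in the 10 gene lists past the camera test, with members past the gene-level test in red and the list median as a black line. The medians run from -0.57 for NF-kB and inflammatory cytokines to 0.91 for replication-dependent histones.

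Stress genes of the unfolded protein and amino acid response had 5 of 23 measured members higher and 0 lower, or 11 higher and 1 lower adjusted over the list alone (median 0.85, camera adjusted p = 0.00117; adjusted p = 0.276 with an estimated correlation). Beside CHAC1, the serine synthesis enzyme PSAT1 rose by 1.71 on the log2 scale from 19.7 ± 3.64 to 68.8 ± 22.3 FPKM (SD, n = 3). Of 22 measured p53 targets 3 rose and 0 fell, or 4 rose and 0 fell adjusted over the list alone (median 0.28, camera adjusted p = 0.13). CDKN1A, the cell cycle inhibitor p21, rose by 1.68 from 21.6 ± 5.64 to 69.8 ± 6.11 FPKM (SD, n = 3), and BTG2, an antiproliferative factor, rose by 2.04 from 3.99 ± 0.861 to 19.4 ± 2.45 FPKM (SD, n = 3). Among 19 measured NRF2 targets 1 rose and 0 fell, the same adjusted over the list alone (median 0.16, camera adjusted p = 0.528). That gene was SLC7A11, the cystine transporter, which rose by 2.17 from 0.941 ± 0.141 to 8.03 ± 2.78 FPKM (SD, n = 3). Xenobiotic metabolism genes, which handle compounds such as NNK, had 1 of 13 measured members higher and 2 lower, or 3 higher and 2 lower adjusted over the list alone (median 0.28, camera adjusted p = 0.923). The full list had 29 members, and CYP2A6, CYP2A13, CYP2B6, CYP2E1, HSD11B1, AKR1C1 and UGT1A1 were among those not measured, so these enzymes were not assessed. The epoxide hydrolase EPHX1 rose by 1.21 and CYP1B1, a cytochrome P450 of the aryl hydrocarbon response, fell by 1.03 from 42.5 ± 4.52 to 20.5 ± 4.06 FPKM (SD, n = 3). GSTA1, a glutathione transferase with close copies, was listed at 2.03, 0.726 and 1.80 FPKM in BEAS-2B and at 0.186, 0 and 0 FPKM in 2B-NNK.

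Cell cycle lists moved little. In the S phase list 1 of 30 measured members rose and 0 fell, the same adjusted over the list alone (median 0.29, camera adjusted p = 0.0258; adjusted p = 0.475 with an estimated correlation). That member was CDT1, which licenses replication origins and rose by 1.43 on the log2 scale from 15.8 ± 4.43 to 43.7 ± 8.002 FPKM (SD, n = 3). The list call was lost without BEAS-2B replicate 3 (camera adjusted p = 0.123), without 2B-NNK replicate 2 (0.0533), with libraries scaled to 1 median (0.0524) and with the most abundant transcript per gene (0.0771). Among 28 measured genes of G2 and mitosis 0 passed the test, also when adjusted over the list alone (median -0.16, camera adjusted p = 0.0173; adjusted p = 0.475 with an estimated correlation). The list did not pass after the GC and length correction (camera adjusted p = 0.0826, median -0.18), after quantile normalization (0.0639) or with the most abundant transcript per gene (0.0679). Its most abundant member, PTTG1, the securin, stood at 338 ± 76.8 and 239 ± 22.7 FPKM (SD, n = 3; log2 fold change -0.48, limma, adjusted p = 0.276). Of 27 measured DNA repair genes 0 passed the test, over all genes or adjusted over the list alone (median 0.03, camera adjusted p = 0.923), and ERCC1 stood at 75.3 ± 19.6 and 64.7 ± 4.14 FPKM (SD, n = 3). Of 19 measured lung cancer drivers and tumour suppressors 0 passed the test, over all genes or adjusted over the list alone, with a median of 0.06, a mean of -0.01 and a camera adjusted p of 0.517. CDKN2A, the most abundant of them, stood at 107 ± 13.1 and 119 ± 32.8 FPKM (SD, n = 3). Cancer-testis antigens had 0 measured members.

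Signalling lists were mixed. Of 24 measured YAP and TGF-beta targets 2 rose and 2 fell, or 2 rose and 6 fell adjusted over the list alone (median -0.53, camera adjusted p = 0.00202; adjusted p = 0.475 with an estimated correlation). The YAP targets ANKRD1 and CTGF rose by 2.28 and 1.19 on the log2 scale, CTGF from 113 ± 25.4 to 258 ± 41.6 FPKM (SD, n = 3). ID1, an inhibitor of differentiation, and the receptor kinase AXL fell by 1.46 and 0.92, AXL from 169 ± 6.88 to 89.9 ± 13.3 FPKM (SD, n = 3). Wnt and Notch genes had 2 of 16 measured members higher and 0 lower, or 4 higher and 0 lower adjusted over the list alone (median 0.50, camera adjusted p = 0.00793; adjusted p = 0.475 with an estimated correlation). The Notch target HES1 stood at 42.3 ± 13.4 and 178 ± 77.9 FPKM (SD, n = 3), a rise of 1.98, and the receptor NOTCH3 at 0.065 ± 0.037 and 0.88 ± 0.144 FPKM (SD, n = 3), a rise of 0.82. After the GC and length correction HES1 had a log2 fold change of 1.88 (SE 0.40, against 0.39 before; limma, adjusted p = 0.056) and NOTCH3 of 0.49 (SE 0.12, against 0.14 before; limma, adjusted p = 0.077), and neither passed. The list also did not pass then (camera adjusted p = 0.0674, median 0.16), and it lost its call without BEAS-2B replicate 3 (camera adjusted p = 0.0509) and without 2B-NNK replicate 1 (camera adjusted p = 0.0699). Of 19 measured genes of ERK pathway output 1 rose and 1 fell, or 3 rose and 4 fell adjusted over the list alone (median -0.16, camera adjusted p = 0.13). These were subunits of the AP-1 transcription factor, FOS rising by 1.40 and FOSL1 falling by 2.40 from 68.6 ± 22.9 to 12.7 ± 5.84 FPKM (SD, n = 3).

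In the hypoxia and glycolysis list 2 of 25 measured members rose and 0 fell, or 2 rose and 2 fell adjusted over the list alone (median -0.20, camera adjusted p = 0.24). PFKFB3, which raises glycolytic flux, rose by 2.00 on the log2 scale from 1.202 ± 0.38 to 7.78 ± 1.04 FPKM (SD, n = 3), and the glucose transporter SLC2A3 was listed at 0.569, 0 and 0 FPKM in BEAS-2B and at 2.17, 2.66 and 2.42 FPKM in 2B-NNK. Of 22 measured cholesterol biosynthesis genes 1 rose and 0 fell, the same adjusted over the list alone. That gene was FDPS, farnesyl diphosphate synthase, which rose by 0.88. The median of this list was 0.00, its mean 0.04 and its camera direction downward (adjusted p = 0.822). Among 13 measured genes of the mitochondrial genome 1 rose and 0 fell, the same adjusted over the list alone (median -0.16, camera adjusted p = 0.831). MT-ND6, the protein-coding gene on the light strand, rose by 0.97 from 214 ± 19.9 to 421 ± 56.9 FPKM (SD, n = 3). Replication-dependent histones, whose mRNAs mostly lack poly(A) tails, had 1 of 13 measured members higher and 0 lower, or 4 higher and 0 lower adjusted over the list alone (median 0.91, camera adjusted p = 0.00694; adjusted p = 0.475 with an estimated correlation). HIST2H2BE rose by 1.12. The histone list was set as a check of RNA quality, and a difference in library preparation between the lines was not tested. Of 28 measured ribosomal protein genes and 14 measured housekeeping genes 0 passed the test, over all genes or adjusted over the list alone (medians -0.15 and -0.09, camera adjusted p = 0.145 and 0.21), and the ribosomal list passed the camera test downward without BEAS-2B replicate 1 (adjusted p = 0.00663). RPL11 stood at 1678 ± 418 and 1537 ± 175 FPKM (SD, n = 3), and RPL13A at 1378 ± 484 and 968 ± 404 FPKM (SD, n = 3).

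Markers of other cell types were few among the listed genes, and their values were given as measured. Adjustment over so few members changes p-values little, and 2348 of all 11423 tested genes had an unadjusted p under 0.05 (limma). Counts adjusted over these lists alone are therefore weak evidence. TPPP3, a ciliated cell marker, was listed at 0.102, 0.043 and 0 FPKM in BEAS-2B and at 2.02, 2.65 and 2.66 FPKM in 2B-NNK and was the 1 of 3 measured ciliated cell markers that rose, while 0 fell, also adjusted over the list alone (median 0.21). ABCA3, a lipid transporter of alveolar cells, rose by 1.26 on the log2 scale as 1 of 3 measured alveolar markers, with 0 lower, or 2 higher and 0 lower adjusted over the list alone (median 0.91). COL1A1, a chain of type I collagen, rose by 1.42 from 92.5 ± 5.13 to 254 ± 60.9 FPKM (SD, n = 3) as 1 of 4 measured fibroblast markers, with 0 lower, or 2 higher and 0 lower adjusted over the list alone (median 0.85). Of 6 measured basal cell markers 0 passed the test, or 1 rose and 2 fell adjusted over the list alone (median -0.67, camera adjusted p = 0.0641), and S100A2 stood at 44.3 ± 21.2 and 18.0 ± 7.11 FPKM (SD, n = 3). The basal list passed the camera test without 2B-NNK replicate 2 (adjusted p = 0.0377). Among 3 measured secretory cell markers 0 passed the test, or 2 rose and 1 fell adjusted over the list alone (median 0.91), with WFDC2 at 14.3 ± 3.41 and 7.96 ± 2.27 FPKM (SD, n = 3). Among 2 measured leukocyte markers 0 passed the test, or 2 rose and 0 fell adjusted over the list alone (median 0.88), with CD14 at 6.55 ± 1.96 and 11.3 ± 2.07 FPKM (SD, n = 3). Of 3 measured neuroendocrine markers 0 passed the test, or 1 rose and 0 fell adjusted over the list alone (median 0.23), with UCHL1 at 111 ± 1.36 and 161 ± 13.7 FPKM (SD, n = 3). The 1 measured marker of hepatocytes and embryonic kidney, SERPINA1, stood at 3.70 ± 1.21 and 2.48 ± 0.742 FPKM (SD, n = 3), and 0 passed the test, also adjusted over the list alone (median -0.42). Endothelial markers had 0 measured members.

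Over the 24 lists with at least 5 measured members, 10 passed the camera test with a preset correlation, 0 with an estimated correlation and 8 after the GC and length correction. The estimates for these 10 lists lay between -0.04 and 0.43, so a call lost with an estimate does not by itself show correlated members. The 10 lists kept their camera direction under each alternative run. The GC and length correction moved other values of the lists. The medians of the NRF2, DNA repair, cholesterol and lung cancer driver lists were then -0.06, -0.01, -0.07 and -0.17. The camera direction, which was not past the test in either case, turned downward for xenobiotic metabolism (median 0.01) and upward for mitochondrial genes (median -0.18). Corrected medians were 0.13 for p53 targets, -0.66 for epithelial junctions and keratins (with 1 of 14 members above 0, against 5 before), -0.34 for matrix proteases, -0.31 for housekeeping genes, -0.09 for ribonucleotide reductase, 0.00 for ciliated markers and 0.04 for neuroendocrine markers. In the hypoxia and glycolysis list 2 members were then higher and 2 lower (median -0.37), and among YAP and TGF-beta targets 2 were higher and 4 lower (median -0.71). Corrected counts were 3 higher and 1 lower for the unfolded protein and amino acid response, 1 higher and 5 lower for NF-kB and cytokines, 2 higher and 0 lower for antigen presentation, for p53 targets, for NRF2 targets and for alveolar markers, 0 higher and 1 lower for secretory markers, and 0 for Wnt and Notch. The other printed lists kept their counts, and their medians moved by less than 1.5 times. By limma's fry, which asks whether the genes of a list move on balance 1 way, 4 lists passed, namely epithelial junctions and keratins, antigen presentation and the unfolded protein and amino acid response (each adjusted p = 0.0089) and interferon response (adjusted p = 0.0351).

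At the level of transcripts, CYBA-201 rose from 0.655, 0.32 and 0 FPKM in the BEAS-2B libraries to 49.0, 77.5 and 53.9 FPKM in the 2B-NNK libraries, a log2 change of 5.53. MCRS1-211, a transcript of a nuclear regulatory protein, was listed at 0 in all 3 BEAS-2B libraries and at 27.3, 16.4 and 16.9 FPKM in 2B-NNK, while MCRS1 as a whole stood at 34.8 ± 9.05 and 36.1 ± 2.11 FPKM (SD, n = 3). MRPL10-201, of a mitochondrial ribosomal protein, was listed at 0.385, 0 and 0 FPKM in BEAS-2B and at 19.2, 14.9 and 17.3 FPKM in 2B-NNK, while MRPL10 as a whole stood at 13.3 ± 8.97 and 18.8 ± 2.09 FPKM (SD, n = 3). KRT7-201, which carried nearly the whole KRT7 signal, fell by 4.32 on the log2 scale. Of 24558 transcripts tested, these and EEF1A2-201, COL6A2-201 and TPM3-206 changed, 6 higher and 1 lower (limma, adjusted p between 0.0401 and 0.0473), while 54 lay at an adjusted p from 0.05 to under 0.06 and 2523 under an unadjusted p of 0.05. Of the 7 genes of these transcripts, 4 also changed at gene level. The transcript count was 1 without BEAS-2B replicate 1, 0 without BEAS-2B replicate 2, BEAS-2B replicate 3, 2B-NNK replicate 2 or 2B-NNK replicate 3, and 14 without 2B-NNK replicate 1. It was 67 after the GC and length correction, 50 and 57 with pseudocounts of 0.1 and 0.5, and 66 with limma without trend or robust settings.

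The authors' deposited table gave a q-value under 0.05 for 44 transcripts, 35 of them higher and 9 lower in 2B-NNK. A p under 0.05 was given by the authors' deposited table for 3000 transcripts, and 1072 of these changed at least 2-fold, 691 higher and 381 lower. For RRM2-201, RRM2-202, RRM2-206 and RRM2-212 the authors' deposited table gave q-values of 0.783, 0.95, 0.659 and 0.766. Of the 42 transcripts with q under 0.05 in the authors' deposited table that were tested here, 4 also passed the limma test of transcripts and 18 belonged to genes changed at gene level.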

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

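The GC and length correction, alone and with the replicate block, was added after the data were seen, and the other alternatives were set before. For 50 named genes past the test, 846 values under an alternative kept their direction, 565 past the threshold and 281 not. Of the counts, 530 changed genes (398 higher, 132 lower), 7 changed transcripts and 10 lists, those not given here moved by less than 1.5 times, and the cause of the moves given here was not tested. With the most abundant transcript per gene 179 genes changed (126 higher, 53 lower), RRM2, through RRM2-202 and its low value in BEAS-2B replicate 3, had a log2 fold change of 0.24 and CDKN2A of -0.17. Lower genes numbered 83 with a mean FPKM of at least 1, higher genes 242 with libraries scaled to 1 median, and lower genes 233 after the GC and length correction. Transcripts numbered 50 and 57 with pseudocounts of 0.1 and 0.5, 14 with a mean FPKM of at least 1, 1 with libraries scaled to 1 median, 66 without trend or robust settings and 67 after the GC and length correction. With an estimated correlation 0 lists passed. Without 1 library at a time, which leaves fewer samples, changed genes ranged from 68 to 281, higher genes from 47 to 200, lower genes from 14 to 81 and transcripts from 0 to 14, while RRM2 ranged from -0.64 to -0.24. Among genes not past the test, the range without 1 library was -0.603 to 0.261 for RRM1, -0.367 to 0.003 for ERCC1, -0.290 to 0.076 for RPL11 and -0.088 to 0.277 for CDKN2A. The sign turned without BEAS-2B replicate 3 for RRM1, ERCC1 and RPL11, without 2B-NNK replicate 2 for RRM1 (0.184) and without 2B-NNK replicate 1 for CDKN2A, which stood at -0.31 after the GC and length correction. Libraries share replicate numbers across lines, and same-numbered libraries correlated in their deviations from the line means at 0.315, 0.072 and 0.065. Of 6 libraries 4 were closest to their own number, so a batch shared by number cannot be excluded. The main fit had no block because the labels state no pairing. With the replicate block 144 genes (106 higher, 38 lower) and 0 transcripts changed, and with the replicate block and the GC and length correction 42 genes (25 higher, 17 lower) and 0 transcripts, with CDKN2A at -0.31. Under the replicate block alone 12 lists passed camera, the mesenchymal and basal cell lists in addition (both downward, adjusted p = 0.0391), and with the GC and length correction as well 8 passed, without G2 and mitosis and without Wnt and Notch (both adjusted p = 0.0665). In the fit without the block, limma put 2523 transcripts under an unadjusted p of 0.05. Count-based tests were not run because the table holds FPKM, and no alternative was run for C2orf48. The unknown depth limits what can be said of low values.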

Other observations

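The tests of GC content, length and scaling, the counts per gene family and the medians per chromosome and window were chosen after the results were seen. Genes of the HOXC cluster, transcription factors of body axis patterning on chromosome 12, were higher in 2B-NNK. Of 7 measured HOXC genes 6 rose and 0 fell (limma, adjusted p under 0.05; median log2 fold change 2.04), and 5 rose after the GC and length correction (median 1.93). HOXC4 rose from 0.175 ± 0.072 to 8.48 ± 0.535 FPKM (SD, n = 3) and HOXC8 from 0.985 ± 0.388 to 15.6 ± 4.51 FPKM (SD, n = 3), while HOXC10 was listed at 0 in all 3 BEAS-2B libraries and at 1.204, 1.5 and 1.08 FPKM in 2B-NNK. Among 7 measured HOXB genes 1 rose and 0 fell (median 0.43), the same counts after the GC and length correction (median 0.25). Of 20 measured collagen chains 5 rose and 0 fell (median 0.34), or 3 rose and 1 fell after the GC and length correction (median 0.16). Complement C4A and C4B, near-identical neighbours that share reads, stood at 0.386 ± 0.195 and 0.463 ± 0.294 FPKM (SD, n = 3) in BEAS-2B and at 9.25 ± 2.41 and 15.5 ± 3.75 FPKM (SD, n = 3) in 2B-NNK. Of 7 measured CXCL chemokines 3 fell and 1 rose (median -1.34).

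Fold changes also followed chromosomal position. After the GC and length correction, the 526 genes of chromosome 5 had a median log2 fold change of -0.23 (-0.22, -0.17 and -0.22 in the 3 2B-NNK libraries against the BEAS-2B mean; shuffled positions -0.07 to 0.02), with 35 genes lower and 7 higher. CSF2 and TGFBI are among the lower genes. Medians were -0.21 on chromosome 18, -0.17 on chromosome 11, 0.14 on chromosome 6 and 0.13 on chromosome 9. Windows of 50 genes overlapped along each chromosome, so counts of windows are not counts of separate regions. In these windows, of which 12 of 420 lay below and 14 above the limits of shuffled positions (-0.29 and 0.29), chromosome 5 was split. The window from 10226442 to 40855456 had a median of 0.47 (0.39, 0.59 and 0.42 in the 3 2B-NNK libraries, and at most 0.11 in size for any BEAS-2B library against the others), and the window from 139781493 to 149366968 had a median of -0.45 (-0.46, -0.39 and -0.52, and at most 0.05). Chromosome 3 from 183967438 to 196439164 had a median of 0.49 and chromosome 11 from 64883875 to 66336067 a median of -0.36. Chromosome 6 from 30687978 to 32148570 had a median of 0.30. Chromosome 5 from 34905369 to 54603550 had a median of 0.49 and chromosome 16 from 4896666 to 18573533 a median of 0.44. Chromosome 16 from 81040103 to 89633236, which spans CYBA and CDT1, had a median of 0.38.

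The fit after the GC and length correction, with 521 changed genes placed, is used in this paragraph. In that fit changed genes lay beside each other more often than chance. Leaving out neighbours whose names share a stem or whose spans overlap, 22 adjacent pairs changed in the same direction, above the upper limit of 17 in shuffled positions (median 11), so shared reads between neighbouring copies cannot be the whole cause. Genes 11 to 50 places apart had fold changes correlated at 0.049, across genes that are not independent, against 0.001 to 0.005 for the 6 differences between libraries of 1 line and -0.003 to 0.003 for shuffled positions. A candidate explanation is a difference in DNA copy number between the lines, such as gain or loss of chromosome segments, which this distance fits, but DNA was not measured and regional chromatin changes were not tested. Single changes such as CSF2, at -3.19 after the correction, were larger in size than any window median, and loss of single genes was not tested.

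More of the changed genes were higher than lower, 75.1% of 530. With each library's trend with GC content and length removed the share was 55.4%, and with libraries scaled to 1 median it was 60.5%. Both settings also centre the fold changes, from a median of 0.07 to -0.02 and -0.03, which evens the balance whatever its cause. A trend with GC content or length, a difference in scaling and a shift of expression in the transformed cells therefore cannot be told apart from these shares. Of the changed genes, 381 remained changed after the GC and length correction.

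Changed genes were many (530) and changed transcripts few, 7 with 54 more at an adjusted p from 0.05 to under 0.06, and 50 to 67 with other pseudocounts, without trend or robust settings or after the GC and length correction. The division of reads among isoforms is a candidate explanation for genes with several listed transcripts. At matched abundance the SD within a line of their transcripts was 2.09 times that of transcripts listed alone. Division of their own reads does not account for 276 of the changed genes, which had 1 listed transcript and so the same value at both levels. For these genes only the moderation of variance and the adjustment differed between the fits. The number of tests cannot be told apart as a further cause, since 361 transcripts lay at or below the largest unadjusted p of a changed gene (0.00231), a value between the bounds set for it. A biological difference in isoform use between the lines was not tested. In the simulation the fit recovered 0% of planted transcript changes of 2 log2 units, against 67% for genes. A low count of changed transcripts therefore does not show that few transcripts differed.

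The 6 libraries allow 10 splits into 3 against 3, too few for a share under 0.05. For changed genes the real split gave 530 and the highest other 4, so 1 of 10 splits gave as many. For changed transcripts it gave 7 and the highest other 65, so that 4 of 10 splits gave as many. The split with 65 set BEAS-2B replicates 1 and 2 and 2B-NNK replicate 1 against the rest, which points to a structure of the samples other than the line. Across genes, the deviation of a library from the gene mean was rank correlated with transcript length at 0.32, 0.18 and 0.12 in those 3 libraries and at -0.26, -0.20 and -0.16 in BEAS-2B replicate 3 and 2B-NNK replicates 2 and 3. Transcripts listed at exactly 0 made up 9.0, 10.8 and 6.3% in the former 3 libraries and 14.6, 13.6 and 12.9% in the latter 3. Whether either difference underlies the split was not tested. For gene lists the real split gave 10 and the highest other 8, so 1 of 10 splits gave as many. The split with 65 transcripts gave 8 lists, as did BEAS-2B replicates 1 and 3 with 2B-NNK replicate 1 against the rest. BEAS-2B replicate 1 with 2B-NNK replicates 2 and 3 against the rest gave 7. Camera at the preset correlation thus called nearly as many lists in some splits that mixed the lines. Each mixed split set 2 libraries of 1 line and 1 of the other against the reverse, so it kept part of the line difference. Lists called in these splits may carry that difference. The line difference also adds to the spread within each side of a mixed split, which lowers its count of changed genes.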
